A study of Arabidopsis thaliana with 4 samples.

How the data were processed

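RNA was measured in guard cells of Arabidopsis thaliana seedlings at 12 days post germination. Per the labels' protocols, aerial tissue was turned into protoplasts, guard cells were collected by fluorescence-activated sorting into extraction buffer, total RNA was purified on micro columns, and cDNA and libraries were made with low-input NuGEN kits. The marker used for the sort, the read length and the strandedness are not given in the sources used here. The 4 libraries fall into 2 genotypes of 2 samples each, wild type (WT) and fama-1 plants carrying FAMA-LGK under the FAMA promoter. Nothing in the labels says that the samples of a genotype came from separate plantings, so p-values measure only the spread between these samples, which may be technical.

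The authors deposited 1 table of TPM values (transcript abundance scaled for gene length and to one total per library) for 33602 genes, made from HTSeq read counts per gene, per the labels. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie2 and HTSeq were used with the TAIR10 genome. The gene lengths behind the TPM values, and the handling of reads that match several places, are not given in the sources used here. Gene names and products came from the TAIR10.1 annotation, which matched 32835 of the 33602 identifiers. The authors' build has another name, so no coordinates are printed.

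TPM keeps no library size. A TPM value made from whole reads is a whole multiple of a step set by the library and the gene's length, so for the 19262 genes with at least 3 values above 0 whole reads were estimated from the ratios of each gene's values between libraries. For 13862 other genes, BASL and CYCD7;1 among them, the nearest whole number at the annotated length was taken (at most 0.0345% of a library's estimated reads), and 478 genes without a length were set to 0 reads, 56 of them with a value above 0. All 19262 came out whole in every sample within a tolerance of 0.005, against 16.7% after 1 sample was shuffled, and 99.4% of 3000 simulated genes were right in all 4 samples. The ratios leave the gene length open: the length found equalled the TAIR10.1 exon length for 11.15% of the genes with whole reads, so read numbers of single genes are approximate. Most simulated genes had their annotated length, so the 99.4% may not carry over to these data, and the estimated totals are approximate too. They were 18271629 and 20524832 reads for WT replicates 1 and 2, and 18188791 and 17934762 for FAMA-LGK replicates 1 and 2. Nuclear genes other than ribosomal RNA held 8404089, 9132188, 6522710 and 8216584 of these reads. Reads without molecular identifiers are not independent molecules, so read numbers and floors cover counting error only. For a gene of 1500 bases, 3 reads correspond to between 0.166 and 0.192 TPM.

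Values were tested as log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (linear model, eBayes with a trend on mean expression, two-sided), with Benjamini-Hochberg adjustment over genes with a mean of at least 1 TPM over the 4 samples and a threshold of 0.05. Fold changes are on this log2(TPM + 1) scale, FAMA-LGK minus WT, which understates the change of low genes. The prior had 7.73 degrees of freedom. With 2 samples against 2, an exact permutation test of a single gene cannot go below a two-sided p of 0.333, so no such test was used. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 14 lists with at least 3 members that passed the minimum, and again with an estimated correlation. That estimate rests on the few residual degrees of freedom of 4 samples, so the second test had little power. A lack of calls in it does not decide whether a list moved. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

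The fit was tested on simulated reads for the same libraries, with 200 genes changed, in 6 simulations of each kind. With the scale of each library held fixed, 3.64% to 8.77% of the genes called were unchanged ones, 35.8% to 51.0% of genes changed 4-fold were called, and 0% to 4.26% of genes changed 2-fold. Benjamini-Hochberg adjustment is less strict where more genes change, and 1907 genes were called in the data. These shares of changed genes called therefore do not carry over to the real fit. With each library forced to one total, as TPM is, between 1 and 74 genes were called, 7.5% to 100% of them unchanged, and 0% to 56.8% of the genes changed 4-fold were called. Median-ratio scaling of those same simulated values brought the unchanged share to between 0% and 7.55%. The first kind of simulation was adopted after the second had shown this weakness, and the deposited TPM values have it in principle. The test planned on TPM as deposited was kept as the main one, and the median-ratio result is given beside it. Every called gene among the changed ones had the right sign, and none of 60 unchanged lists was called in any kind of simulation. Simulated genes varied independently and the unchanged lists were random genes. False calls of lists whose members vary together were therefore not tested.

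The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names FAMA and RBR1, the members of the early stomatal lineage and guard mother cell lists, the 10 highest and 10 lowest genes by fold change among called genes with both FAMA-LGK values on the same side of both WT values and at least 10 TPM in the higher genotype (organelle and ribosomal RNA genes left out), and up to 4 members with the smallest p of each other list. MYB60, BCA4, CPK3, JAZ1, KCS1, KCS20, LSU1, LSU2 and APR1 were named after their values were seen. The other settings fixed at that point were pseudocounts of 0.1 and 5, no filter and a minimum of 5 TPM, median-ratio and quantile scaling, removal of organelle genes, variance without a trend and with robust estimation, a replicate block, leaving out each library, and the estimated correlation. Removal of ribosomal RNA with organelle genes, removal of a length and GC trend, and voom weights on the estimated reads were added after seeing the data. Reads of overlapping genes on opposite strands cannot be told apart here, since the counting is not stated to use strand; among named genes with such a partner are SMR5, AT1G04800, KNOLLE, RNR2A, POLAR, HDG2, ERL1, LHCB6, TCX2, TCX3, ORC1A, AT2G39518 and HSP101. Named genes were searched with BLAST 2.17.0 for copies at 90% identity or more over at least 30% of their length. The counts of reads differed between the 2 samples of each genotype by more than sampling noise (chi-square per degree of freedom 23.6 in WT and 81.3 in FAMA-LGK, over genes with at least 20 reads), so no library was a second copy of another.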

Results

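Gene expression was compared between sorted guard cells of WT seedlings and of fama-1 seedlings carrying FAMA-LGK, a form of the guard cell transcription factor FAMA altered in its motif for binding the retinoblastoma-related protein RBR1. The series describes the first as fully differentiated and the second as reprogrammed guard cells, and the comparison asks how their transcripts differ. Each genotype had 2 libraries, of an estimated 17934762 to 20524832 reads. Across genes, log2(TPM + 1) correlated at 0.970 between the WT libraries, 0.952 between the FAMA-LGK libraries and 0.885 to 0.898 between genotypes. The first principal component held 68.1% of the variance and separated the genotypes; PC2, with 19.5%, separated the FAMA-LGK libraries. Organelle genes took 27.8% and 25.3% of TPM in WT replicates 1 and 2, and 29.8% and 30.8% in FAMA-LGK. Nuclear ribosomal RNA took 24.2% and 27.2% in WT, 33.0% in FAMA-LGK replicate 1 and 22.3% in replicate 2. The 10 highest genes held 43.8%, 44.4%, 52.5% and 42.2% of TPM in the same order, and 13495, 13137, 13472 and 13338 genes were at 0.

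FAMA-LGK guard cells differed from WT in 1907 of 15143 genes tested, 977 higher and 930 lower (limma, adjusted p threshold 0.05). By at least 1 log2 unit, 820 were higher and 763 lower, and by at least 3 units 23 were higher and 59 lower. Median-ratio scaling called 2285 genes, among them 1887 of the 1907, with 44.8% of calls higher against 51.2% as deposited. Removal of ribosomal RNA and organelle genes, chosen after seeing the data, called 2249, with 67.2% higher, and moved the median of all genes from 0.06 to 0.24. The calls rest on both WT libraries: without WT replicate 1 or without WT replicate 2, limma called 0 genes, with 2675 and 2365 at an unadjusted p under 0.05 and lowest adjusted p of 0.0614 and 0.0553. This holds for each gene named below as changed, since all 59 of them lost the call in both of these fits, in which the lone WT library is assumed to vary like the FAMA-LGK libraries. Without FAMA-LGK replicate 2, 611 genes were called higher and 1074 lower, 36.3% of them higher. Without a filter on low values 511 genes were called, and 39 of the 59 named genes kept their call.

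FAMA (AT3G24140) transcripts were present in both genotypes, at 65.9 ± 0.370 TPM in WT and 87.8 ± 9.24 in FAMA-LGK (SD, n = 2 libraries each). The log2 fold change of 0.40 (SE 0.20, limma adjusted p = 0.224) did not pass the test. Reads of the mutant locus and of the transgene cannot be told apart in a value per gene. RBR1 (AT3G12280) was at 16.2 ± 0.797 TPM in WT and 13.4 ± 1.24 in FAMA-LGK (log2 fold change -0.25, limma adjusted p = 0.535).

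SPCH (AT5G53210), the transcription factor that starts the stomatal lineage, rose from 4.05 and 2.88 TPM in the WT libraries to 26.6 and 42.2 in the FAMA-LGK libraries (log2 fold change 2.96, SE 0.30, limma adjusted p = 2.9e-04). Of 13 measured genes of the early stomatal lineage list, 4 were higher, 1 was lower and 8 were not called; adjusted over the list alone, 7 were higher and 1 lower. SDD1, a protease that limits stomatal density, rose by 1.22 log2 units (adjusted p = 0.0162), the polarity gene POLAR by 1.17 (adjusted p = 0.0326) and the receptor-like protein gene TMM by 0.90 (adjusted p = 0.0182). SCRM, which encodes a partner of SPCH, was lower (log2 fold change -0.75, SE 0.20, adjusted p = 0.0349). The members without a call were SCRM2 (log2 fold change 0.53), ERL1 (1.19), ERL2 (-0.71), EPF2 (0.73), BRXL2 (0.90), HDG2 (0.78), TCX2 (-0.06) and TCX3 (-0.05). Voom called 6 higher and 1 lower, adding ERL1 (adjusted p = 0.0202) and HDG2 (0.0436); ERL1 was also called without a variance trend (0.0444) and HDG2 with ribosomal RNA and organelle genes removed (0.0437). The list median was 0.78 and camera called it higher (adjusted p = 0.0208, but adjusted p = 0.656 with an estimated correlation). Without FAMA-LGK replicate 1 the list's adjusted p was 0.0855, SDD1 was at 0.0695, POLAR at 0.0528 and SCRM at 0.0630. Without FAMA-LGK replicate 2, POLAR was at 0.128 and SCRM at 0.0597. With organelle genes removed, SCRM was not called (adjusted p = 0.0714, and 0.113 with ribosomal RNA removed too). Without FAMA-LGK replicate 1 the list had 2 higher and 0 lower, without replicate 2 3 and 0, and without a filter 1 and 0. POLAR and ERL1 each overlap a gene on the opposite strand. BASL, below the minimum, was at 0 TPM in 3 libraries and 2.13 in FAMA-LGK replicate 2, about 28 reads at its annotated length.

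**Figure D1:**
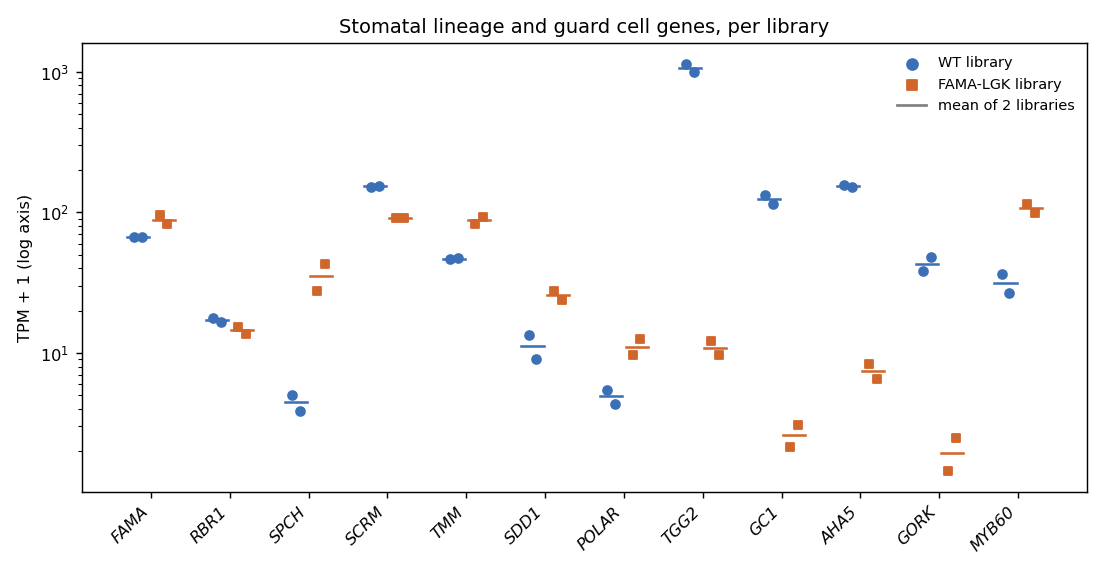
TPM + 1 on a log axis for 12 genes in each of the 4 libraries, circles for WT, squares for FAMA-LGK and bars for the mean of 2 libraries; MYB60 was chosen after its value was seen. TGG2 lies at 1138.8 and 991.7 TPM in WT and at 11.2 and 8.62 in FAMA-LGK, whereas SPCH lies at 4.05 and 2.88 in WT and at 26.6 and 42.2 in FAMA-LGK.

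Of the 7 measured genes of the guard mother cell list, limma called 0, also when adjusted over the list alone, against 1 at an unadjusted p under 0.05 and 0 with voom, and camera did not call the list (median 0.47, adjusted p = 0.370). FLP, a MYB gene that limits guard mother cell division, was at 1.12 ± 0.322 TPM in WT and 3.26 ± 0.161 in FAMA-LGK (limma adjusted p = 0.102). The log2 fold changes were -0.85 for EPF1, 0.19 for MYB88, 0.32 for CYCD5;1, 0.47 for SMR4, 0.77 for CDKB1;1 and 0.70 for CYCA2;3. Leaving out 1 library gave -1.46 to -0.24 for EPF1 and 0.065 to 0.87 for SMR4. CYCA2;3 was at 8.65 TPM in FAMA-LGK replicate 1 and 3.14 in replicate 2, with a CYCA2;3 log2 fold change of 0.085 without replicate 1 and an adjusted p of 0.0593 without replicate 2. MUTE, below the minimum, had 1 and 3 estimated reads in WT and 14 and 9 in FAMA-LGK. CDKB1;2 had 4 and 13 in WT and 1 and 26 in FAMA-LGK, and CYCD7;1 was at 0 TPM in 3 libraries and 0.0794 in FAMA-LGK replicate 2, about 1 read at its annotated length.

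Of 34 measured genes of mature guard cell function, 13 were lower in FAMA-LGK, by up to 108-fold as a ratio of mean TPM. The myrosinase gene TGG2 (AT5G25980) fell from 1065 ± 104 TPM to 9.89 ± 1.81 (log2 fold change -6.62, SE 0.21, limma adjusted p = 7.6e-07), and GC1 from 123.5 ± 13.1 to 1.61 ± 0.679. GORK, the outward potassium channel, was at 42.1 ± 6.69 TPM in WT and 0.953 ± 0.732 in FAMA-LGK (adjusted p = 4.8e-05). The proton pump gene AHA5 was at 152.9 ± 4.06 and 6.45 ± 1.26 TPM (adjusted p = 7.9e-06). A further 3 were higher and 18 not called; adjusted over the list alone, 16 were lower and 4 higher. The 3 higher ones, named after their values were seen, were MYB60, a guard cell transcription factor, at 30.6 ± 7.10 and 106.2 ± 10.8 TPM, BCA4 at 26.6 ± 1.43 and 101.8 ± 8.81, and CPK3 at 21.2 ± 5.36 and 38.5 ± 0.322. CPK3 lost its call without FAMA-LGK replicate 1 (adjusted p = 0.102) and without FAMA-LGK replicate 2 (0.0931), and with a pseudocount of 0.1 (CPK3 log2 fold change 0.88, adjusted p = 0.0529). Without a filter 8 members were lower and 2 higher. The list median was -0.35 (-0.70 without WT replicate 2, -0.61 without FAMA-LGK replicate 2 and -0.21 with ribosomal RNA and organelle genes removed) and camera called it lower (adjusted p = 2.2e-05, but adjusted p = 0.656 with an estimated correlation).

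Among the 10 highest genes by fold change, LTP1 (AT2G38540), a lipid transfer protein, rose from 4.54 and 3.41 TPM in WT to 136.2 and 102.6 in FAMA-LGK (log2 fold change 4.59, SE 0.25, limma adjusted p = 8.7e-06). It was followed by AT5G55180, a glycosyl hydrolase (log2 fold change 4.47), HR4 (3.91), the NAC factor NAC047 (3.88), AT2G39518 (3.86), the peroxidase PRXCB (3.73), ACA2 (AT2G28210), an alpha carbonic anhydrase (3.67), the ribonuclease RNS1 (3.66), the jasmonate synthesis gene AOC1 (3.66) and the invertase ATBFRUCT1 (3.53). AT2G39518 rested on 7 and 0 estimated reads in WT, against 139 and 153. After TGG2, the lowest were AT1G04800, a glycine-rich protein (-5.74), GC1 (-5.60), AT4G24340 (-5.57), AT5G25840 (-5.35), RGLG3 (-5.28), ZPR3 (-5.14), RAB7A (-5.14), the sucrose synthase SUS3 (-5.09) and AT1G55210 (-4.81). AT1G04800 shares 40.6% of its annotated length with a gene on the opposite strand, and reads of the shared part cannot be told apart. That gene was at a mean of 9.19 TPM in WT and 9.61 in FAMA-LGK, against 4482 and 82.5 for AT1G04800. AT4G24340 is 90.7% identical to a neighbour over 44.7% of its length, so the value of AT4G24340 is uncertain to that extent. RAB7A rested on 2 and 12 estimated reads in FAMA-LGK.

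Genes of abscisic acid synthesis and signalling went both ways. The receptor gene PYL2 fell from 63.1 ± 10.4 to 4.26 ± 2.23 TPM (log2 fold change -3.67, limma adjusted p = 1.1e-04) and PYL4 from 133.1 ± 10.2 to 53.4 ± 3.26 (adjusted p = 0.00293). ABI2, a phosphatase of the pathway, was lower by a log2 fold change of -1.52 (adjusted p = 0.0107), whereas CYP707A3, an enzyme that breaks the hormone down, rose by 2.04 (adjusted p = 4.7e-04). Of 27 measured members, 3 were higher, 7 lower and 17 not called; adjusted over the list alone, 3 were higher and 8 lower. Over all genes 3 were higher and 4 lower without FAMA-LGK replicate 1, 1 and 6 without replicate 2, and 1 and 2 without a filter. Camera did not call the list (median -0.03, adjusted p = 0.170), except without FAMA-LGK replicate 2 (median -0.28, adjusted p = 0.0410).

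Of 22 measured genes of mitosis and cytokinesis, 5 were higher in FAMA-LGK, at low levels, 0 lower and 17 not called. The cytokinesis syntaxin KNOLLE rose from 8.39 and 6.55 TPM in WT to 16.4 and 16.5 in FAMA-LGK (log2 fold change 1.05, limma adjusted p = 0.0260) and the kinesin gene HIK from 5.08 and 2.90 to 11.4 and 11.6 (1.36, adjusted p = 0.0199). CDKB2;1 was higher, at 2.93 TPM in WT and 9.17 in FAMA-LGK on average (adjusted p = 0.0305), as was CDC20.1, at 2.03 and 5.96 (adjusted p = 0.0374), the latter 97.0% identical to its neighbour over 65.1% of its length. Of KNOLLE's annotated length, 33.5% overlaps NPQ1 on the opposite strand. Adjusted over the list alone, 7 were higher; over all genes 1 was higher without FAMA-LGK replicate 1, 1 without replicate 2 and 0 without a filter. The list median was 0.67 and camera called it higher (adjusted p = 0.00106, but adjusted p = 0.700 with an estimated correlation). Without FAMA-LGK replicate 1 the list's adjusted p was 0.0691, and HIK, KNOLLE, CDKB2;1 and CDC20.1 were at 0.0708, 0.0760, 0.135 and 0.0907. Without FAMA-LGK replicate 2, HIK, KNOLLE and CDC20.1 were at 0.0661, 0.0698 and 0.0963.

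Genes of G1 entry and DNA replication were not called as a list (median 0.16, camera adjusted p = 0.770). Of 19 measured members, 1 was higher, 1 lower and 17 not called; adjusted over the list alone, 0 were higher and 1 lower. RNR2A, a ribonucleotide reductase subunit, fell from 43.4 ± 8.76 to 7.91 ± 1.67 TPM (limma adjusted p = 4.9e-04), and overlaps a gene on the opposite strand whose mean went from 22.1 to 2.4 TPM. CDT1A, a replication licensing gene, rose by 1.19 (adjusted p = 0.0480), and was at 0.0726 and 0.159 without FAMA-LGK replicate 1 and 2 and at 0.0543 with a pseudocount of 0.1; with robust variance it lay just above the threshold, without a call. ORC1A and CDT1B had log2 fold changes of 0.83 and 0.82 without a call. Among 10 measured inhibitors of cyclin-dependent kinases, 2 were higher, 1 lower and 7 not called, and 2 were higher and 3 lower adjusted over the list alone (median -0.20, camera adjusted p = 0.370). SMR5 was at 57.0 and 42.8 TPM in WT and 3.84 and 3.82 in FAMA-LGK (adjusted p = 5.7e-05), but lies within a gene on the opposite strand whose mean went from 54.2 to 31.1 TPM. SMR8 rose from 6.62 and 4.92 TPM to 17.1 and 14.2 (adjusted p = 0.0139) and was at 0.0686 without FAMA-LGK replicate 1. SMR2, the other one called higher, had 1 and 0 estimated reads in WT and 16 and 15 in FAMA-LGK, and was not called with voom (adjusted p = 0.0533). KRP3 had a log2 fold change of -1.21 without a call.

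Of 26 measured genes of Polycomb, trithorax and histone demethylases, limma called 0, also when adjusted over the list alone, against 1 at an unadjusted p under 0.05 and 1 with voom (median -0.03, camera adjusted p = 0.770). The call with voom was VEL1 (adjusted p = 0.0296), which was also called lower under median-ratio scaling (0.0298), with a minimum of 5 TPM (0.0460) and with the length and GC trend removed (0.0275). The smallest p were those of VEL1 (log2 fold change -0.78, limma adjusted p = 0.0571), VRN5 (-0.92), EMF1 (-0.44) and BMI1A (0.43). Leaving out 1 library gave -1.39 to -0.44 for VRN5, and 1 member was called higher without FAMA-LGK replicate 1. Of 28 meristem, embryo and flower regulators known as Polycomb targets, 24 lay below the minimum, the highest at 0.665 TPM in any library. The 4 measured ones, AGL15 (-0.86), PI (0.64), WIND1 (-0.09) and WOX2 (0.10), were not called, also when adjusted over the list alone, against 1 at an unadjusted p under 0.05 and 0 with voom (median 0.01, whereas the mean was -0.05 and camera's direction was down, adjusted p = 0.770).

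Of 10 measured genes marking the epidermis and its pavement cells, 6 were higher in FAMA-LGK and 4 not called. Besides LTP1, PDF1 rose from 6.99 ± 0.629 to 23.2 ± 3.93 TPM (log2 fold change 1.59, limma adjusted p = 0.00352), the epidermal identity factor ATML1 from 8.31 ± 1.59 to 24.4 ± 1.17 (adjusted p = 0.00514) and FDH, an enzyme of wax and cutin synthesis, from 50.6 ± 15.5 to 122.6 ± 10.2 (adjusted p = 0.00861). Without FAMA-LGK replicate 1 the list had 4 higher, without replicate 2 5 and without a filter 3. Adjusted over the list alone, 9 were higher (median 1.09, camera adjusted p = 1.1e-05, but adjusted p = 0.656 with an estimated correlation). Mesophyll photosynthesis markers had a median of -0.29 (-0.16 without FAMA-LGK replicate 1, -0.44 without replicate 2 and -0.11 with ribosomal RNA and organelle genes removed): 1 of 20 was lower, LHCB6, at 35.2 ± 0.901 and 18.0 ± 3.96 TPM (adjusted p = 0.0287), and 0 adjusted over the list alone, against 6 at an unadjusted p under 0.05 and 1 called with voom. LHCB2.1, LHCB1.3 and LHCB4.1 had log2 fold changes of -0.68, -0.58 and -0.48 without a call; with the length and GC trend removed, LHCB1.3 (adjusted p = 0.0421) and LHCB4.1 (0.0395) were called and 3 of the list were lower. Camera called the list lower (adjusted p = 0.0136, but adjusted p = 0.700 with an estimated correlation), and not without WT replicate 2 (0.195) or FAMA-LGK replicate 1 (0.0855, LHCB6 0.0913) or with ribosomal RNA and organelle genes removed (0.0563). All 5 trichome markers and all 12 phloem and xylem markers lay below the minimum, at most at 0.968 and 1.79 TPM in any library.

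**Figure D2:**
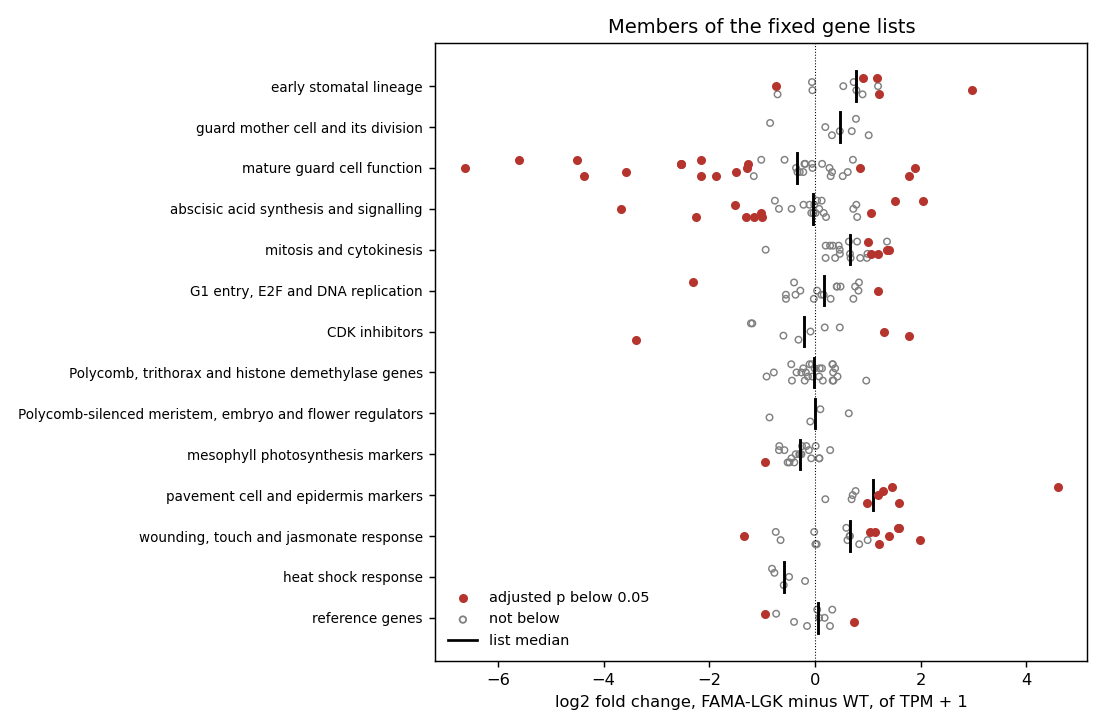
Log2 fold change of TPM + 1, FAMA-LGK minus WT, for each measured member of 14 gene lists, filled where the limma adjusted p was below 0.05, with the list median as a bar. Members of the guard cell list reach down to -6.62, and all 10 epidermal members lie above 0.

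Of 19 measured genes of the response to wounding, touch and jasmonate, 7 were higher in FAMA-LGK, 1 was lower and 11 were not called. The jasmonate synthesis genes LOX3 and AOS rose from 42.9 ± 4.72 to 172.3 ± 5.36 TPM (limma adjusted p = 3.0e-04) and from 9.94 ± 0.964 to 31.4 ± 4.02 (adjusted p = 0.00265), the cell wall enzyme gene TCH4 by 1.41 log2 units (adjusted p = 0.00297) and WRKY40 by 1.59 (adjusted p = 0.00562). JAZ1, a repressor of the jasmonate response named after its value was seen, was lower, at 1935 ± 684 and 734 ± 59.6 TPM (adjusted p = 0.0172), and was at 0.0661 without FAMA-LGK replicate 1 and, with ribosomal RNA and organelle genes removed, at 0.0535 with a JAZ1 log2 fold change of -1.16. Without FAMA-LGK replicate 2 the list had 5 higher and 1 lower, and without a filter 4 and 0. Adjusted over the list alone, 13 were higher and 3 lower (median 0.66, camera adjusted p = 0.00106, but adjusted p = 0.656 with an estimated correlation). Of 7 defence genes, 5 lay below the minimum. CYP81F2 and MYB51 were not called over all genes (limma adjusted p = 0.0528 and 0.103), but both were higher adjusted over these 2 alone. Their levels were low and uneven. CYP81F2 was at a mean of 0.0755 TPM in WT, and at 3.45 and 1.33 in FAMA-LGK replicates 1 and 2. MYB51 was at 0.246, 4.53 and 1.04 in the same order. Leaving out 1 library gave log2 fold changes of 1.12 to 2.05 for CYP81F2 and 0.72 to 2.15 for MYB51. CYP81F2 was called with voom (adjusted p = 0.0262) and with organelle genes removed (0.0348).

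Heat shock transcripts were abundant in all 4 libraries, and limma called 0 of 5, also when adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 with voom (median -0.59, camera adjusted p = 0.196). HSP90.1 was at 4390 and 4922 TPM in WT, 1712 in FAMA-LGK replicate 1 and 4088 in replicate 2, and HSP101 at 2040, 2723, 850 and 2873. HSP70-4 was at 3738, 4170, 2079 and 3799, and HSP17.6II at 2239, 3762, 882 and 3290. Without FAMA-LGK replicate 2 the list was lower (adjusted p = 0.00255) and 3 of its genes were called lower, HSP90.1 (adjusted p = 0.0368), HSP17.6II (0.0262) and HSP101 (0.0244), and without replicate 1 its median was 0.18 (adjusted p = 0.936). Of 10 reference genes, ACT8 was higher (0.73, limma adjusted p = 0.0386), ACT7 lower (-0.94, adjusted p = 0.0305) and 8 not called, with 1 higher and 1 lower adjusted over the list alone; GAPC1 was at -0.73 (called under median-ratio scaling, adjusted p = 0.0476, and with voom, 0.0403) and ACT2 at 0.33. ACT8 and ACT2 are 91.2% identical over 59.2% of ACT8. Without FAMA-LGK replicate 1, ACT7 was at 0.102 and ACT8 at 0.0579, and without replicate 2 ACT8 was at 0.0776. The list median was 0.06 whereas camera's direction was down (adjusted p = 0.770).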

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

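The removal of ribosomal RNA with organelle genes, the removal of the length and GC trend, and voom were chosen after seeing the data. The count of 1907 called genes stayed within 1.5 times under 12 of 13 alternatives that kept all libraries, and fell to 511 without a filter (245 higher, 266 lower), where 23227 genes were tested. Genes called higher numbered 1512 with ribosomal RNA and organelle genes removed, where rescaling moved the median of all genes from 0.061 to 0.243. Genes called lower numbered 595 without a variance trend, and the cause of that was not tested. Leaving out 1 library gave 0 to 1685 calls, 0 to 816 higher and 0 to 1074 lower, and 3 to 8 lists called by camera. With an estimated correlation camera called 0 lists, with 0 at an unadjusted p under 0.05. With 4 samples this setting had little power, so its lack of calls does not decide about any list. The numbers of the samples were not taken to pair them, since same-numbered deviations correlated at 0.078; with a replicate block 2844 genes were called, 1479 higher and 1365 lower, the mesophyll list was at an adjusted p of 0.0760, and KRP3, VEL1, CYP81F2 and MYB51 were called. FAMA kept its direction without a call in every alternative and left-out library, with log2 fold changes from 0.30 to 0.60.

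The correlation between WT libraries was 0.947 and 0.983 with pseudocounts of 0.1 and 5 and 0.955 with voom; between FAMA-LGK libraries it was 0.921 and 0.971 with those pseudocounts, 0.966 without a filter, 0.932 with ribosomal RNA and organelle genes removed and 0.934 with voom. Of the 59 named genes with a call, 59 kept it under median-ratio scaling, quantile normalization and length and GC removal, 39 without a filter and 47 without a variance trend. SCRM, TMM, POLAR, SDD1, KNOLLE, CDKB2;1, CDT1A, LHCB6, ACT7, ACT8, CPK3 and JAZ1 lost it in both of these, and HIK, CDC20.1, ABI2, SMR8, SMR2, FDH, WRKY40 and APR1 without a filter alone. In these settings, no named gene or list called on the values as deposited turned its sign. Among named genes without a call, with ribosomal RNA and organelle genes removed TCX2 turned to 0.082, TCX3 to 0.11 and WIND1 to 0.10. The TCX3 log2 fold change was 0.0087 with organelle genes removed. With quantile normalization WOX2 was at -0.031. Leaving out 1 library gave log2 fold changes from -0.20 to 0.088 for TCX2, -0.21 to 0.11 for TCX3, -0.27 to 0.090 for WIND1, -0.23 to 0.44 for WOX2, -1.72 to 0.18 for HSP17.6II and -1.47 to 0.29 for HSP101. The mitosis median was 0.32 and 1.03 with pseudocounts of 5 and 0.1. Over all settings list medians ranged from 0.42 to 1.08 for the early stomatal lineage, 0.20 to 0.72 for the guard mother cell and -0.32 to -0.079 for inhibitors of cyclin-dependent kinases. Without 1 library they ranged from -0.015 to 0.32 for G1 and from -1.44 to 0.18 for heat shock, with camera's direction turned at -0.015 and at 0.18. Camera's direction also turned for G1 with a minimum of 5 TPM (median -0.023), and, with medians of unchanged sign, for G1 with ribosomal RNA and organelle genes removed (0.40) and for reference genes there (0.25) and with quantile normalization (0.090). Medians close to 0 turned without a turn of camera's direction, over all settings from -0.28 to 0.18 for abscisic acid, -0.15 to 0.16 for Polycomb and trithorax genes, -0.25 to 0.26 for Polycomb targets and -0.030 to 0.25 for reference genes. The cause was not tested. Estimated depth limits what can be said of MUTE, BASL and CYCD7;1, with at most 28 reads in any library.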

Other observations

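The gene families here were written after the lists had been examined, and all tests of explanations in this part were chosen after the results were seen. Of 39 families tested with camera, genes of sulphur deficiency and sulphate assimilation were lower in FAMA-LGK: of 17 measured, 6 were lower and 1 higher (median -0.67, adjusted p = 3.6e-04, but adjusted p = 0.844 with an estimated correlation). The sulphur deficiency gene LSU1 fell from 238 to 14.4 TPM, LSU2 from 712 to 139 and APR1, a reductase of sulphate assimilation, from 729 to 302. Among ketoacyl-CoA synthases, which elongate fatty acids for waxes, 6 of 12 were higher and 0 lower (median 0.83, adjusted p = 0.00173, but adjusted p = 0.844 with an estimated correlation), with KCS1 at 35.8 and 379 TPM and KCS20 at 90.4 and 344; FDH is in this family and in the epidermal list. Mitochondrial electron transport genes had 6 of 43 lower (median -0.44, adjusted p = 4.8e-04, but adjusted p = 0.844 with an estimated correlation). Camera also called photosystem genes lower (5 of 47, median -0.25, adjusted p = 0.00173, 0.107 without WT replicate 2; medians from -0.32 to -0.069 under 4 scalings) and kinesins and leucine-rich repeat receptor kinases higher (medians 0.62 and 0.39, adjusted p = 0.0149 and 0.0442), all at an adjusted p of 0.844 with an estimated correlation. Of 38 kinesins 1 was called higher, and the family was at 0.107 without WT replicate 2, 0.110 without FAMA-LGK replicate 1 and 0.242 with a minimum of 5 TPM (median 0.27). Of 56 receptor kinases 7 were higher and 3 lower, and the family was at 0.135 and 0.168 without these libraries, 0.247 without a filter, 0.0674 with the length and GC trend removed, 0.0817 with a replicate block and up to 0.115 under other scalings. The directions of the sulphur, ketoacyl-CoA synthase and electron transport families held under 4 scalings, with medians from -0.74 to -0.52, 0.62 to 0.80 and -0.51 to -0.25, and their camera calls held without each library.

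Of 34 mature guard cell genes, 13 were lower in FAMA-LGK; mesophyll cells in place of guard cells would raise mesophyll markers, whose median was -0.29 (SD 0.303 over 20 markers; medians from -0.44 to -0.11 over all settings), although guard cells also have chloroplasts. Removal of ribosomal RNA and organelle genes with rescaling kept 13 of the 13 calls, as did removal of the length and GC trend. Those genes were picked for their calls, so the kept calls are weak evidence. The median of those 13 genes went from -2.53 to -2.34 and -2.53. These moves are small against the fall, which argues against either as the whole cause. Phloem and xylem cells as the whole cause would bring their abundant transcripts, but the highest of 12 markers was at 1.79 TPM in FAMA-LGK, below the medians of all tested genes, 6.46 and 7.47. Pavement cells in place of guard cells cannot be told apart from the genotype by the list values, because the sort and the genotype coincide. The list median was -0.35 and its mean -1.09 (standard error of the mean 0.341). Dilution by such cells would lower all guard cell transcripts alike, yet 3 of the 34 members were higher, MYB60 among them. Another 18 were not called, which does not show that they were not lowered. Log2 fold changes were below 0 for 24 of the 34 members and above 0 for 10. Members with expression outside guard cells would not be diluted, and which members have it was not tested. FAMA, whose value may include transgene reads, was at 65.9 TPM in WT and 87.8 in FAMA-LGK. Pavement cells, trichome cells, whose markers are regulators and not abundant transcripts (at most 0.578 TPM), and the genotype, as a biological explanation not tested apart from them, stay open. Cells at an earlier stage of the stomatal lineage were not tested as an explanation and stay open too.

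Of 10 epidermal genes, 6 were higher in FAMA-LGK. Median-ratio scaling kept 6 of the 6 calls. Those genes were picked for their calls, and this scaling moved the median of all genes only from 0.061 to -0.0041. That move is small against the list median of 1.09, so the calls could hardly have been lost. The kept calls therefore do not decide about library scale. Pavement cells in the FAMA-LGK sort and a change within the sorted cells cannot be told apart by the list median of 1.09, because the sort and the genotype coincide and no library of pavement cells was analysed here. Such cells would dilute guard cell transcripts, yet 3 guard cell members were higher; members with expression outside guard cells would not show this. In FAMA-LGK, LTP1 and FDH were at 119.4 and 122.6 TPM and FAMA at 87.8. The sort was aimed at guard cells, but its marker is not given in the sources used here and its purity was not tested.

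All 5 heat shock genes were lower in FAMA-LGK replicate 1 than in replicate 2, with a median log2 difference of -1.32, a level reached by 2.95% of tested genes; all 5 were also lower in WT replicate 1 than in WT replicate 2, by a median of -0.17, a level reached by 26.2% of genes. The median difference of all tested genes was -0.16, which argues against library scaling as the cause. Handling of the cells before lysis may contribute and stays untested, and no biological explanation was tested, since both libraries have one genotype.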
